A study of Mus musculus with 9 samples.

How the data were processed

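The series holds 9 samples of mouse MLL-AF9 cells carrying an inducible TGIF1-ER construct. Per the labels' protocols, lysates were sonicated to a mean fragment length near 300 bp, E. coli DNA was added to the precipitate as carrier up to 2 ng, and libraries were made with a NEB Next kit for Illumina sequencing. The antibodies were a TGIF antibody (H-172) and a Meis antibody. Each was applied to cells treated with EtOH or with 4-OHT for 20 h, with 2 libraries in each of the 4 groups. Groups and replicate numbers were taken from the sample titles.

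The deposited files hold peak positions, 1 list per library, so peaks were called on single libraries. Per the submitters' processing notes, the build was mm9 and Bowtie 0.12.7 was used. MACS 1.4.2 is named per the file headers of 1 list (MEIS1 4-OHT replicate 2). The caller of the other lists, the threshold, the control library and any filters are not given in the sources used here. Each deposited list gives chromosome, start, end, length and summit, and the values showed that length equals end minus start plus 1 in all peaks. No score, height, fold enrichment, p-value or read number was in the lists, and all peaks lay on the 19 autosomes and X. The depth per library is therefore unknown, and peak number, peak length and overlap all depend on it. Lists ranged from 592 to 48829 peaks, a ratio of 82.5, and median peak length ranged from 283 to 633 bp. No 2 lists of a group shared an identical interval.

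Peaks of the 2 libraries of a group were merged where they overlapped by at least 1 bp, and merged regions with a peak from both libraries were called reproducible. The design fixed before the data were examined used the authors' score to rank peaks. As the lists had none, the length rank within each list took its place in the length classes, in the stricter threshold and in the rule for named regions. This rule took the 10 reproducible regions with the best mean rank in each of 6 sets: TGIF1 4-OHT, MEIS1 EtOH, MEIS1 4-OHT, regions shared by TGIF1 4-OHT and MEIS1 EtOH, and TGIF1-bound MEIS1 regions lost or gained under 4-OHT. The text gives coordinates of none of the MEIS1 4-OHT set, and of the MEIS1 EtOH set only where they were also named as shared regions. Of the other sets it gives some. All coordinates are mm9, counted from 1. Gene lists and sequence motifs had also been planned, but an annotation and sequence of mm9 were not used here, so neither was run and no gene is named.

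Peak numbers were compared by the log2 ratio of the group means with a two-sided exact permutation test. Shares of overlapping regions were compared with 1000 circular shifts of the regions, each chromosome moved by its own random step, one-sided. A MEIS1 region was lost when no peak of either 4-OHT library overlapped it, gained in the mirror case, and TGIF1-bound when it overlapped a reproducible TGIF1 4-OHT region. Odds ratios were taken over 5 classes of mean length rank with the two-sided exact conditional Cochran-Mantel-Haenszel test, threshold 0.05. For the largest tables, in 2 of the alternatives for gain, the exact distribution could not be computed numerically and the asymptotic test took its place. Intervals of shares are exact (Clopper-Pearson, 95%) and cover counting error only.

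The alternatives were a reciprocal overlap of 50%, peak centres within 200 bp, the longer part of each list (the upper 50% by length), lists of equal length (592 TGIF1 and 21173 MEIS1 peaks), the union of replicates, each library left out in turn with the other standing for its group, values within each replicate number, placement within 1 Mb, odds ratios without length classes, and TGIF1 binding restricted to regions without a TGIF1 peak under EtOH. A further pair, without chromosome 15 and without loci of recurrent long peaks, were chosen after seeing the data.

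Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, R 4.3.3 and bedtools 2.31.1 were used. The overlap code was checked against bedtools and gave equal counts in 112 of 112 comparisons. The odds ratio test was tested on simulated data: loss was drawn for the 22793 reproducible MEIS1 EtOH regions with true odds ratios of 0.5, 1 and 2, in 20 simulations each. The median estimates were 0.489, 0.998 and 1.97, and 20, 2 and 20 of the simulations passed the threshold. Each region was drawn independently, from 1 base rate per length class. Dependence between regions and length differences within a class were therefore not covered. For the overlap test, 1 of 40 random placements of the 11143 TGIF1 regions passed it, and a planted overlap of 40% was measured as 41.2%. The placements were made by the same shifts that the test itself uses. They check the code, and not whether such shifts suit real peaks.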

Results

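Chromatin immunoprecipitation followed by sequencing was carried out in mouse MLL-AF9 cells, which are c-kit-positive bone marrow cells of C57BL/6 mice transformed by the leukaemia fusion oncogene MLL-AF9. The cells also carried TGIF1-ER, the homeodomain repressor TGIF1 joined to the estrogen receptor, whose activity is switched on by 4-hydroxytamoxifen (4-OHT). Cells treated with 4-OHT for 20 h were set against cells given ethanol (EtOH). The series held no 4-OHT-treated cells without TGIF1-ER. Effects of 4-OHT itself therefore cannot be told apart from those of TGIF1 activity. Binding of TGIF1 and of MEIS1, a homeodomain protein of the same TALE class and a known cofactor of HOX proteins in leukaemia, was measured in 2 libraries per treatment and antibody. Peak lists of these 8 libraries were analysed. The 9th sample, a non-specific IgG precipitation, was not analysed here. The lists gave positions only, so the sequencing depth of each library was unknown. Nothing in the labels said whether the 2 libraries of a group came from separate cultures, so the spread given between them may be technical.

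TGIF1 peaks were far more numerous after induction. The TGIF1 EtOH libraries held 2764 and 592 peaks, and the TGIF1 4-OHT libraries held 12141 and 26932 peaks. The mean rose from 1678 ± 1536 (SD, n = 2) to 19536.5 ± 10459 (SD, n = 2), a ratio of 11.6, or 3.54 on the log2 scale. Both induced libraries exceeded both EtOH libraries, but 2 against 2 libraries cannot give less than 0.333 in a two-sided exact permutation test, and p was 0.333. The ratio depended on single libraries: it was 33.0 without TGIF1 EtOH replicate 1, 7.07 without TGIF1 EtOH replicate 2 and 7.24 without TGIF1 4-OHT replicate 2.

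**Figure D1:**
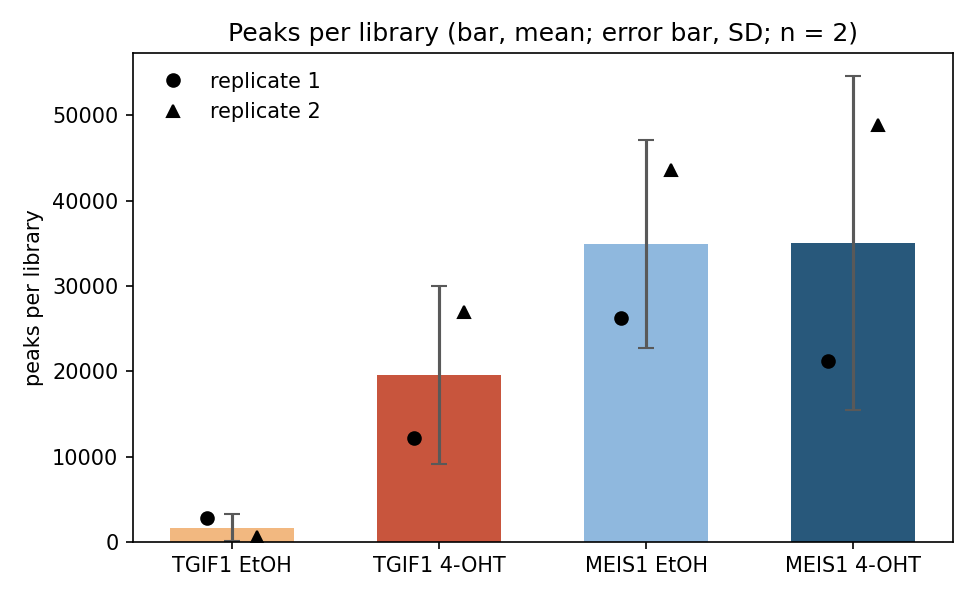
Number of peaks (vertical axis) in each of the 8 libraries, by antibody and treatment; bars are means, error bars the SD of 2 libraries, circles replicate 1 and triangles replicate 2. The TGIF1 means were 1678 under EtOH and 19536.5 under 4-OHT, while the MEIS1 means were 34909 and 35001.

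Most sites of TGIF1 under EtOH also carried a peak after induction. A peak in at least 1 TGIF1 4-OHT list was found at 2521 of the 2764 peaks (91.2%) of TGIF1 EtOH replicate 1 and at 553 of the 592 (93.4%) of replicate 2. Of the 463 reproducible TGIF1 EtOH regions, those with a peak in both libraries, 459 (99.1%, exact 95% interval 97.8 to 99.8%) carried one. Reproducible TGIF1 4-OHT regions numbered 11143, and 8795 of them (78.9%, exact 95% interval 78.2 to 79.7%) had no TGIF1 peak in either EtOH library. The replicates differed mainly in how much was called: 96.5% of the peaks of TGIF1 4-OHT replicate 1 overlapped replicate 2, against 41.4% in the other direction. By the rule for named regions, which ranked regions by length within their lists, the leading TGIF1 4-OHT region lay on chromosome 12 from 117486719 to 117490732 (mm9). It had a TGIF1 peak in both induced libraries and no peak in any of the 6 other lists. The second, on chromosome 1 from 87493794 to 87498157, carried peaks in 7 of the 8 lists, and so did regions on chromosome 7 from 16893667 to 16899622 and on chromosome 11 from 119900750 to 119904223. The region on chromosome 1 lies in a 1-Mb window where peaks of at least 3 kb recurred in 5 lists, and ranking by length favours such places. A region on chromosome 19 from 7091379 to 7094238 was the only one of the 10 named with a peak in all 8 lists.

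MEIS1 peak numbers did not separate the treatments. The MEIS1 EtOH libraries held 26254 and 43564 peaks (mean 34909 ± 12240, SD, n = 2), and the MEIS1 4-OHT libraries held 21173 and 48829 (mean 35001 ± 19556, SD, n = 2). The log2 ratio of the means was 0.0038, less than the spread between replicates (two-sided exact permutation p = 1.0). The direction turned with single libraries: the log2 ratio was -0.32 without MEIS1 EtOH replicate 1 and -0.72 without MEIS1 4-OHT replicate 2. Without MEIS1 EtOH replicate 2 it was 0.41, and without MEIS1 4-OHT replicate 1 it was 0.48. Reproducible MEIS1 regions numbered 22793 under EtOH and 19864 under 4-OHT. Of the EtOH regions, 15897 (69.7%, exact 95% interval 69.1 to 70.3%) overlapped a reproducible 4-OHT region.

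The series examined where TGIF1 and MEIS1 bind in these cells, and the sites of the 2 proteins were widely shared. Of the 11143 reproducible TGIF1 4-OHT regions, 6791 (60.9%, exact 95% interval 60.0 to 61.9%) overlapped a reproducible MEIS1 EtOH region, and 5680 (51.0%) overlapped a reproducible MEIS1 4-OHT region. For the EtOH regions, shifting the TGIF1 regions along their chromosomes gave a mean of 1.56% and at most 2.09% (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). By TGIF1 library, the share with reproducible MEIS1 EtOH regions was 58.6% for TGIF1 4-OHT replicate 1 and 45.4% for replicate 2 (mean 52.0 ± 9.33%, SD, n = 2). With reproducible MEIS1 4-OHT regions it was 48.8% and 37.0% (mean 42.9 ± 8.35%, SD, n = 2). Against the single MEIS1 library of the same number the order turned. The shares were then 56.5% for replicate 1 and 72.5% for replicate 2 with MEIS1 EtOH, and 47.3% and 73.0% with MEIS1 4-OHT. With a reciprocal overlap of 50% required, the share with MEIS1 EtOH regions was 36.6%, against at most 0.481% in shifted regions. A MEIS1 peak in at least 1 of the 4 MEIS1 lists was present at 9907 TGIF1 regions (88.9%), which left 1236 (11.1%, exact 95% interval 10.5 to 11.7%) with none. Of the 8795 TGIF1 4-OHT regions without a TGIF1 peak under EtOH, 5202 (59.1%) overlapped a MEIS1 EtOH region, beside 1589 of 2348 (67.7%) of those with one. The TGIF1 EtOH lists were short and their depth was unknown, so a missing peak there does not show that TGIF1 was absent. A list for IgG was not used here, so the share of these sites that any antibody would recover was not measured.

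In the other direction, 6801 of the 22793 reproducible MEIS1 EtOH regions (29.8%, exact 95% interval 29.2 to 30.4%) overlapped a reproducible TGIF1 4-OHT region. Shifted regions gave a mean of 0.766% and at most 1.00% (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). By MEIS1 library, the share with reproducible TGIF1 4-OHT regions was 27.8% for MEIS1 EtOH replicate 1 and 22.4% for replicate 2 (mean 25.1 ± 3.77%, SD, n = 2). Against the single TGIF1 4-OHT library of the same number it was 26.6% for replicate 1 and 44.6% for replicate 2. TGIF1 was found most often at long MEIS1 regions: with MEIS1 regions in 5 equal classes of length rank, it was present at 51.7% of the longest class, 36.1%, 29.0% and 19.7% of those between, and 12.6% of the shortest. The share rose to 52.2% without TGIF1 4-OHT replicate 1. With every list of an antibody reduced to the length of its shortest, which kept 592 TGIF1 peaks per library, it was 0.875%.

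**Figure D2:**
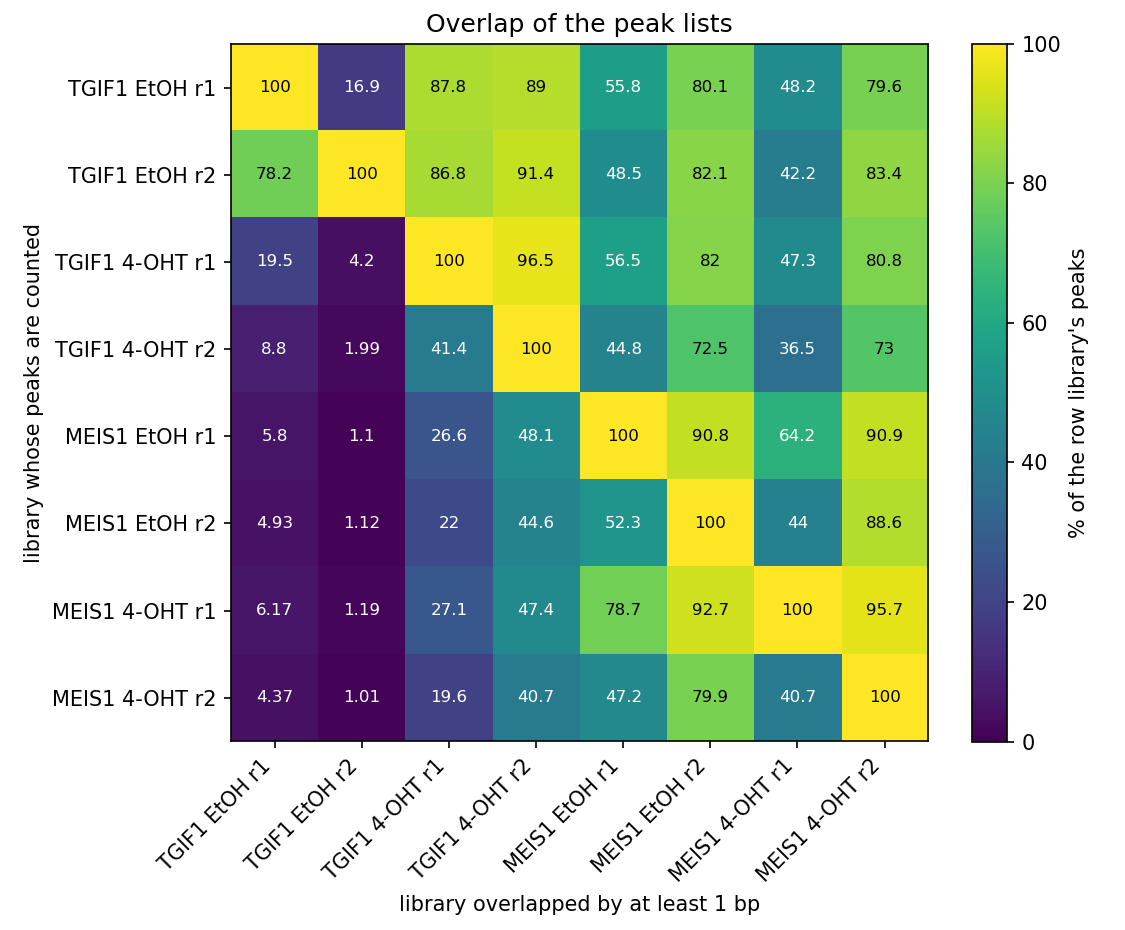
Percent of the peaks of each library (rows) that overlap a peak of another library (columns) by at least 1 bp; r1 and r2 are the replicates. Of TGIF1 4-OHT replicate 1 peaks, 96.5% overlap TGIF1 4-OHT replicate 2 and 82.0% overlap MEIS1 EtOH replicate 2, while 19.5% overlap TGIF1 EtOH replicate 1.

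Regions shared by both proteins were led by chromosome 1 from 87491490 to 87498185, chromosome 1 from 85105215 to 85110377 and chromosome 1 from 90172224 to 90175360. Further down the list were chromosome 15 from 8468057 to 8470285, chromosome 11 from 78471274 to 78473264 and chromosome 3 from 107821804 to 107823867, each with a peak in both TGIF1 4-OHT libraries and all 4 MEIS1 libraries and none in the TGIF1 EtOH libraries. A region on chromosome 7 from 106683254 to 106685782 carried peaks in all 8 lists. The first 2 of these regions lie in 1-Mb windows where peaks of at least 3 kb recurred in at least 4 lists. Leaving out such windows and their neighbours left the shared part of the TGIF1 regions at 60.9%.

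Within overlapping peaks, the summits of TGIF1 and MEIS1 lay close together. This comparison was chosen after the data were seen. The median distance was 28 to 31 bp over the 8 pairs of a TGIF1 4-OHT with a MEIS1 library, and 59.9 to 67.2% of the pairs of summits were within 50 bp. Reassigning the relative summit positions among the peaks of each list gave medians of 75.4 to 117 bp (one-sided permutation p = 0.001 in each of the 13 comparisons, the smallest that 1000 draws can give, and 0.001 after Benjamini-Hochberg adjustment). Summits of the same protein were closer still, with medians of 14 to 17 bp between replicates and 13 to 16 bp between MEIS1 EtOH and MEIS1 4-OHT libraries of the same number. Overlapping peaks are not independent, and these values describe the libraries compared. No list for IgG or for an unrelated protein was compared, so whether the closeness is particular to TGIF1 and MEIS1 was not measured.

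**Figure D3:**
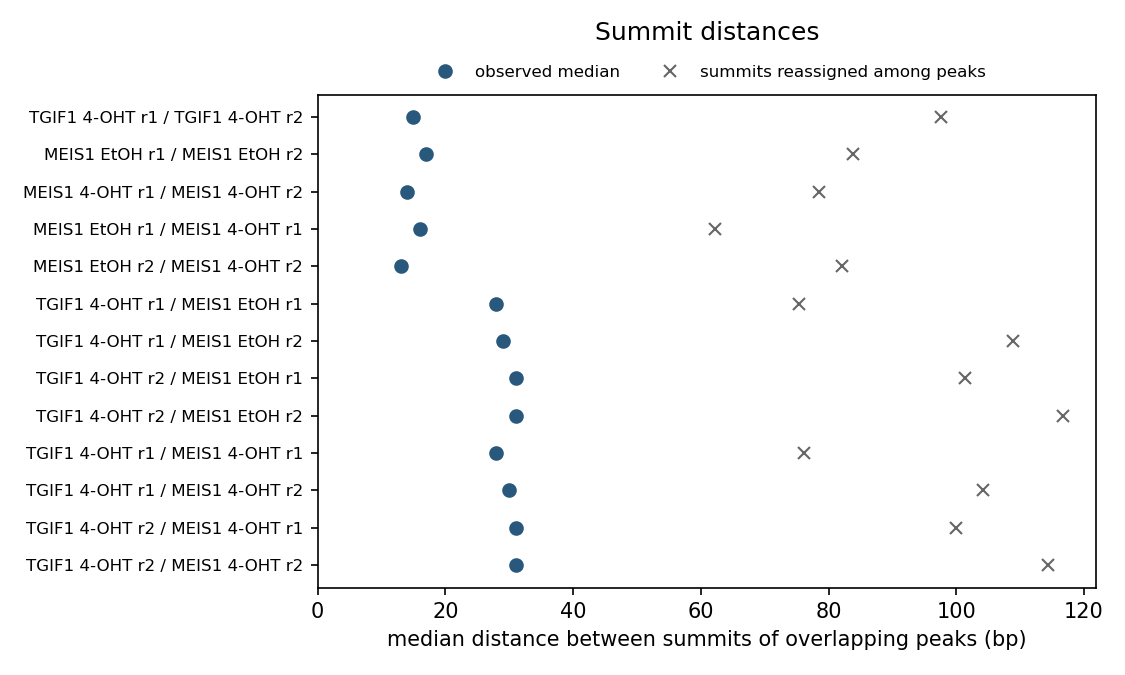
Median distance in bp (horizontal axis) between the summits of overlapping peaks for 13 pairs of libraries (rows); circles are observed medians and crosses the mean median after reassigning relative summit positions among peaks. All TGIF1 and MEIS1 pairs lie between 28 and 31 bp, and their crosses between 75.4 and 117 bp.

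Few reproducible MEIS1 regions were absent from both libraries of the other treatment, and the share depended on single libraries. Of the 22793 reproducible MEIS1 EtOH regions, 664 (2.91%, exact 95% interval 2.70 to 3.14%) had no MEIS1 peak in either 4-OHT library. The peaks of a single MEIS1 EtOH library were absent from both 4-OHT libraries in 8.08% of cases for replicate 1 and 10.9% for replicate 2 (mean 9.47 ± 1.97%, SD, n = 2). As the spread between replicates, 9.20% of the peaks of MEIS1 EtOH replicate 1 were absent from replicate 2 and 47.7% the other way round. These are absences from 1 library, which are more frequent than absences from both. The like share for 1 EtOH library against 1 4-OHT library was 9.11 to 56.0% over the 4 pairs. The lost share was 29.9% without MEIS1 4-OHT replicate 2, whose list is the longest, 10.9% without MEIS1 EtOH replicate 1 and 8.08% without MEIS1 EtOH replicate 2. In the mirror comparison, 640 of 19864 reproducible MEIS1 4-OHT regions (3.22%, exact 95% interval 2.98 to 3.48%) had no MEIS1 peak in either EtOH library. For single 4-OHT libraries this share was 5.46% for replicate 1 and 18.4% for replicate 2 (mean 11.9 ± 9.13%, SD, n = 2). Peaks of 1 4-OHT library were absent from 1 EtOH library in 7.28 to 52.8% of cases over the 4 pairs. Between the 4-OHT replicates, 4.29% of replicate 1 peaks were absent from replicate 2 and 59.3% the other way round. The gained share was 18.7% without MEIS1 EtOH replicate 2, 18.4% without MEIS1 4-OHT replicate 1 and 5.46% without MEIS1 4-OHT replicate 2.

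MEIS1 regions that TGIF1 also occupied were lost less often than the rest. Loss was seen at 93 of 6801 TGIF1-bound MEIS1 EtOH regions (1.37%, exact 95% interval 1.11 to 1.67%) and at 571 of 15992 without TGIF1 (3.57%, exact 95% interval 3.29 to 3.87%). Within the 5 classes of region length the odds ratio was 0.704 (95% interval 0.554 to 0.886; two-sided exact conditional Cochran-Mantel-Haenszel p = 0.0023). For the peaks of 1 library absent from 1 other, the odds ratio ranged from 0.323 to 0.729 over the 4 pairs of an EtOH with a 4-OHT library. Between the EtOH replicates, where no treatment differed, it was 0.177 for replicate 1 peaks absent from replicate 2 and 0.526 for the reverse, so TGIF1-bound peaks were less often absent there too, and the ranges overlapped. The odds ratio was 0.823 (exact p = 0.061) without MEIS1 4-OHT replicate 1, 0.946 (exact p = 0.12) without MEIS1 4-OHT replicate 2 and 0.299 without MEIS1 EtOH replicate 2. It was 0.809 (exact p = 0.139) with a reciprocal overlap of 50%, 0.374 without length classes, and with lists of equal length 0.961 (exact p = 1.0), resting on 2 lost TGIF1-bound regions.

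Gains of MEIS1 were also rarer at TGIF1-bound regions than at the rest. They were seen at 31 of 5713 TGIF1-bound MEIS1 4-OHT regions (0.543%, exact 95% interval 0.369 to 0.769%) and at 609 of 14151 without TGIF1 (4.30%, exact 95% interval 3.98 to 4.65%). The odds ratio was 0.220 (95% interval 0.148 to 0.318; two-sided exact conditional Cochran-Mantel-Haenszel p = 1.8e-23). For the peaks of 1 library absent from 1 other, it ranged from 0.124 to 0.464 over the 4 pairs of a 4-OHT with an EtOH library, and was 0.279 and 0.524 between the 4-OHT replicates. Leaving out libraries moved the value to 0.546 without MEIS1 EtOH replicate 2 and to 0.129 without MEIS1 4-OHT replicate 2, and with lists of equal length it was 0.993 (exact p = 1.0). Without length classes it was 0.121. Regions are not replicates, so these p-values measure the sampling of regions within these libraries and not the spread between cultures.

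**Figure D4:**
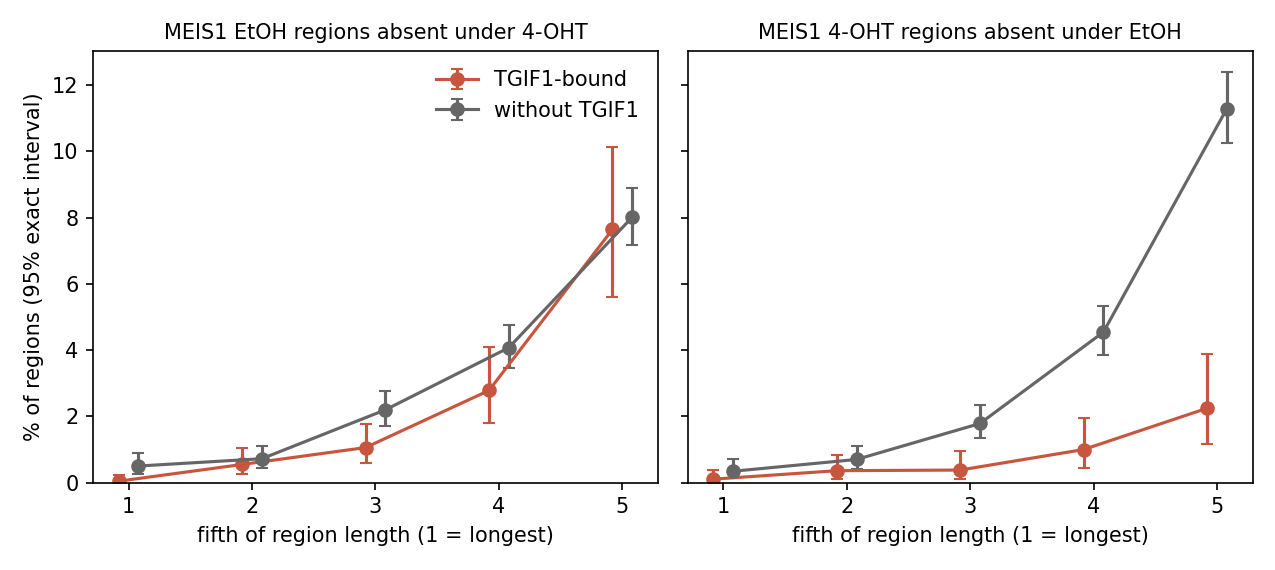
Percent of reproducible MEIS1 regions absent from both libraries of the other treatment (vertical axis), by class of region length from 1 (longest) to 5 (shortest), for TGIF1-bound regions (red) and regions without TGIF1 (grey); error bars are exact 95% intervals that cover counting error only. In the shortest class, 7.64% of TGIF1-bound EtOH regions were absent under 4-OHT against 8.01% without TGIF1, and 2.24% of TGIF1-bound 4-OHT regions were absent under EtOH against 11.3% without TGIF1.

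The lost regions with TGIF1 were led by chromosome 19 from 25197443 to 25198276, which carried a TGIF1 peak also under EtOH, chromosome 15 from 78429369 to 78430573 and chromosome 9 from 40152143 to 40153098. These regions were 834, 1205 and 956 bp long. All 10 named lost regions had peaks in both MEIS1 EtOH libraries, by definition, and in both TGIF1 4-OHT libraries, which the definition makes likely but does not require. The gained regions with TGIF1 were led by chromosome 5 from 125866457 to 125868679, which at 2223 bp was the longest of its 10, chromosome 5 from 105886967 to 105887876 and chromosome 15 from 98815581 to 98816645. The genes next to these regions were not named, because an annotation of the mm9 build was not used here.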

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

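Both induced TGIF1 lists were longer than both EtOH lists, and keeping 50% of each list leaves a ratio of list lengths as it is. The alternatives therefore could not turn the direction of the TGIF1 peak number ratio and say nothing about the stability of that direction. The size of the ratio was not stable: leaving out single libraries gave 7.07 to 33.0. Both shares of overlap between TGIF1 and MEIS1 stayed above random placement in all 13 alternatives. They ranged from 36.6% (reciprocal overlap of 50%) to 85.0% for TGIF1 4-OHT regions and from 0.875% (lists of equal length) to 52.2% for MEIS1 EtOH regions. Random placement put regions anywhere on a chromosome or within 1 Mb, whatever lies there, and gave small shares. Staying above it therefore says little about stability, or about a link particular to these 2 proteins. The gain odds ratio stayed below 1 and past the threshold in 15 of 16 and was 0.993 with lists of equal length, which left 2 gained TGIF1-bound regions. The MEIS1 peak number ratio had no stable sign: leaving out single libraries gave log2 ratios from -0.72 to 0.48. The lost share of MEIS1 regions was 5.90% with the longer part of each list and 13.4% with the union of replicates, and leaving out single libraries gave 3.34 to 29.9%. The gained share, added after seeing the data, was 19.1% with the union, and leaving out single libraries gave 4.37 to 18.7%. The loss odds ratio stayed below 1 in all 16 alternatives but did not pass the threshold in 4: a reciprocal overlap of 50% (0.809), lists of equal length (0.961), without MEIS1 4-OHT replicate 1 (0.823) and without MEIS1 4-OHT replicate 2 (0.946). Leaving out single libraries gave 0.299 to 0.946. Lists of equal length hold few TGIF1 regions; the cause of the other changes was not tested. The odds ratio of TGIF1 binding in EtOH-only against 4-OHT-only MEIS1 regions, added after seeing the data, was 3.08 and turned to 0.722 with lists of equal length, and leaving out single libraries gave 0.535 to 6.69.

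Replicate numbers are shared between groups, but nothing shows that they pair the libraries. Presence of a peak in replicate 1 minus replicate 2 correlated between treatments across regions (r = 0.282 for TGIF1 and 0.227 for MEIS1), and regions are not replicates. These correlations cannot decide on pairing, because the lists differed in length. MEIS1 replicate 2, for example, was the longer list under both treatments, and regions called only in longer lists can give a positive value without pairing. With the replicate block, the MEIS1 log2 ratio was -0.073, the lost share 23.6% and the gained share 20.7%, since 1 library then stands for each treatment; no other result changed its direction or its side of the threshold. Gene lists, motifs and classes of distance to a gene start were not run, and no list held other chromosomes. Unknown depth limits all peak numbers and absences.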

Other observations

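The test of library differences and the alternatives without chromosome 15 and without recurrent long peaks were chosen only after the result was seen. TGIF1 regions without MEIS1 were mostly short. The share of reproducible TGIF1 4-OHT regions with no MEIS1 peak in any of the 4 lists was 3.14% (70 of 2228) in the longest of 5 length classes and 22.7% (506 of 2229) in the shortest. Of the 272 regions of at least 2 kb, 6 lacked MEIS1, and 4 of these were among the 10 named TGIF1 regions: chromosome 12 from 117486719 to 117490732, chromosome 13 from 58447621 to 58451461, chromosome 1 from 153647187 to 153650304 and chromosome 15 from 80070181 to 80072951. None of the 4 had a TGIF1 peak under EtOH. A TGIF1 peak under EtOH was present at 11.7% of the regions without MEIS1 and at 22.2% of those with it.

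Long peaks recurred at few places. Of the 140 peaks of at least 3 kb among all 182249 peaks, 54 lay in 6 windows of 1 Mb where at least 4 lists had such a peak. The windows starting at 85000001 and 87000001 on chromosome 1 held 17 and 10 of them, and the one starting at 47000001 on chromosome 6 held 14. TGIF1 EtOH lists held 7 of the 140.

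Among MEIS1 regions present under 1 treatment, those of EtOH carried TGIF1 more often: 93 of 664 EtOH-only regions (14.0%) and 31 of 640 4-OHT-only regions (4.84%), an odds ratio of 3.08 (95% interval 1.99 to 4.88) within length classes. Loss itself was rarer at TGIF1-bound regions than at the rest (odds ratio 0.704 within length classes), and gain was rarer still (0.220). The 3.08 therefore does not show that TGIF1-bound regions were lost more often than others. TGIF1-bound peaks were also less often absent between EtOH replicates, so the loss odds ratio does not decide on displacement. Displacement of MEIS1 by induced TGIF1 is a candidate explanation, and differences in yield between libraries are another. The mean log odds ratio over the 4 pairs of an EtOH with a 4-OHT library was 0.682, below the 0.853 by which MEIS1 EtOH replicate 2 exceeded replicate 1, but larger in size than the -0.335 of MEIS1 4-OHT replicate 1 against replicate 2. The odds ratios of the 4 pairs were 1.45 and 2.77 for same-numbered libraries, 1.00 (95% interval 0.863 to 1.16) for MEIS1 EtOH replicate 1 with 4-OHT replicate 2, and 3.81 for MEIS1 EtOH replicate 2 with 4-OHT replicate 1; libraries in each pair differed in peak number and median peak length, so yield was matched in none. Over 3 equal classes of TGIF1 region length the odds ratio was 2.63 (95% interval 0.959 to 8.38) in the longest, 5.89 (2.22 to 19.7) in the middle one and 2.47 (1.42 to 4.47) in the shortest, overlapping intervals that do not decide on displacement. With 2 libraries per treatment the explanations cannot be told apart, and without MEIS1 EtOH replicate 2 the direction turned (0.535).

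Peaks on chromosome 15 were longer than elsewhere in all 8 lists. Its mean length percentile over the 6 lists of TGIF1 4-OHT and MEIS1 was 61.5 ± 2.34 (SD over lists), the highest of the 20 chromosomes, followed by 55.4 ± 2.10 on chromosome 3; X was lowest at 33.2 ± 2.52. Crowding of peaks was argued against: matched on the number of peaks within 100 kb, chromosome 15 still exceeded the other autosomes by 6.67 to 14.7 percentile points. Extra copies of chromosome 15 may raise read numbers and peak length; the matched difference was above 0 in 10 of 11 windows of 10 Mb, and the exception, -2.24 ± 8.38 (SD over lists), was within its spread. The difference was 1.97 in the first window and 16.4 in the one starting at 70000001, and no read numbers of an input library were used here, so extra copies and other regional properties cannot be told apart. Without chromosome 15 the loss odds ratio was 0.712 and the shared part of TGIF1 regions 60.5%. For chromosome 15, no biological explanation that differs between the groups was tested.

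MEIS1 EtOH regions with another MEIS1 region within 12.5 kb carried TGIF1 in 32.3% (3780 of 11694), and isolated ones in 27.2% (3021 of 11099). Within length classes the odds ratio was 1.13. Moving the TGIF1 regions by up to 1 Mb gave a mean of 1.27 and up to 2.12 over 1000 draws (one-sided permutation p = 0.815), so the observed value did not exceed the draws. Such moves of the TGIF1 regions left a mean of 2.87% of them at a MEIS1 EtOH region, against 60.9% observed. The draws thus rest on far fewer TGIF1-bound regions. They cannot show whether clustering of both proteins along the chromosomes accounts for the excess at neighbouring regions.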
